A study of Homo sapiens with 4 samples.

How the data were processed

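The data are RNA sequencing of total RNA from SW1990 cells, with 2 libraries after 100 nM erianin for 48 h and 2 after DMSO. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a standard Illumina method. The submitters' processing notes name fastp, STAR, StringTie 2.2.1, featureCounts 2.0.1 and the build GRCh38, with no role or order. The annotation, the strandedness and the rule for reads that match several genes are not given in the sources used here.

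The deposited count table has 107429 rows for 25798 gene IDs, with no transcript names, and 14076 IDs have more than 1 row. Rows of the same gene, such as GAPDH and ACTB, hold very unequal large values, which look like reads apportioned between overlapping transcripts, so the values were treated as estimated counts. The rows of a gene ID were summed. The estimated counts were deposited by the authors as whole numbers, not normalized, and per the submitters' processing notes StringTie and featureCounts were among the tools used. The plan made before the data were examined had assumed plain counts per gene. The deposited FPKM table has the same rows in the same order, and per the file headers its values are FPKM per library. In 465 to 481 genes with 1 row and 1 annotated transcript, count, FPKM and length implied a library total of which the table's counts make up 85 to 87%.

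Gene symbols came from a table of gene names, which held 25779 of the IDs, 20932 of them with a symbol. Positions, GC content and length of the longest transcript came from GENCODE release 29 on GRCh38, which held 24725 of the IDs and 97.8% of the genes tested. Coordinates are 1-based.

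The main test was edgeR 4.0.16 (R 4.3.3) on the summed counts, with TMM factors (1.04, 1.03, 1.01 and 0.928 for DMSO replicates 1 and 2 and erianin replicates 1 and 2), filterByExpr at its default minimum count of 10, which left 17090 genes and removed 8708. Genes were tested with the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design held the group only, with 2 residual degrees of freedom. Standard errors are the log2 fold change divided by the square root of F. The biological coefficient of variation was 0.233. CPM values are counts scaled to the TMM-adjusted library size. Folds for genes at 0 in a group use a floor of 3 counts per library, and such floors cover counting error only.

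Gene lists, 20 in number, were fixed before the data were examined: mitosis, DNA replication, tubulin, p53 targets, FOXO targets, AP-1 and stress kinase response, ATF4 targets, ER chaperones, NRF2 targets, apoptosis regulators, cholesterol synthesis, glycolysis, autophagy and lysosome, YAP and SRF targets, mesenchymal, epithelial, interferon response, NF-kB and inflammatory cytokines, other cell types (fibroblast, blood and endothelial markers) and mitochondrial transcripts. Each was tested two-sided with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 20 lists. The test was repeated with an estimated correlation, where 0 of 20 passed (smallest adjusted p = 0.694). That form of the test uses the 2 residual degrees of freedom, so it has little power whatever the correlation. The mitochondrial list, with an estimated correlation of -0.00196, below the preset 0.01, went from an unadjusted camera p of 3.04e-06 to 0.0386. Failing it therefore decides little, and the p-values at the preset correlation stay uncertain. The named genes were also fixed by rule. They include AKT1, AKT2 and MAP3K5, then up to 8 genes with the largest rise and up to 8 with the largest fall among protein-coding genes past the threshold with a symbol other than a clone or locus name, a mean log2 CPM of at least 3 and groups that do not overlap, and from each list up to 3 members past the threshold with a mean log2 CPM of at least 1 or, with none, the member with the smallest p. One gene of the rule is not reported here. Only RAB4B-EGLN2 met the rule for large changes. Further list members were chosen as examples after their values had been seen.

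Genes that share at least 200 nucleotides at 95% identity with a gene past the threshold were found with BLAST+ 2.17.0 among the GENCODE transcripts and are called its partners. To remove a trend with GC content and length, the log2 CPM of each library less the mean of all libraries was fitted with natural splines (5 degrees of freedom) on genes with a mean log2 CPM of at least 3. The fitted value was used as an offset.

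The edgeR and camera steps were tested on simulated data, with 5 draws of 200 changed genes at the dispersions of this comparison and no GC trend. Among 16506 genes tested, 24.2% of genes changed by 1.5-fold, 65.1% of those changed by 2-fold and 98.2% of those changed by 4-fold were recovered. The changed genes were drawn from those with a mean log2 CPM of at least 1, so these rates do not cover genes below that. Of the calls, 69 of 713 calls were of genes simulated without a change. A list of 20 genes shifted by 0.5 was found in 5 of 5 draws and a random list in 0 of 5. Genes were drawn independently, and the shifted list came from genes with a mean log2 CPM of at least 4. Estimated correlations of the real lists past the threshold ran from -0.00196 (mitochondrial transcripts) to 0.95 (tubulin), and most of their medians were smaller than 0.5 in size. The draws therefore do not show how often such lists are found or falsely called.

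Alternatives were other scalings, filters and tests (DESeq2 1.42.0, limma-voom, and limma on the deposited FPKM with pseudocounts of 1 and 0.1), the replicate number as a block, each library left out, the removal of the GC and length trend, overlapping genes summed, and the rows as deposited.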

Results

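RNA sequencing measured transcript levels in 4 libraries of SW1990, an established human pancreatic adenocarcinoma line. Cells of 2 libraries had received 100 nM erianin for 48 h, and cells of the other 2 had received DMSO, the solvent. Erianin is a plant bibenzyl known to bind tubulin and to disturb microtubules. The deposited counts added up to 63254725 and 60798427 in the DMSO libraries and to 63336545 and 59923935 in the erianin libraries. At least 1 count was found for 21583, 21194, 21109 and 20519 gene IDs in DMSO replicates 1 and 2 and erianin replicates 1 and 2.

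The comparison of erianin with DMSO asked which transcripts differ after exposure to the compound, in a study whose title names AKT and ASK1 as its targets. Of 20 gene lists, 7 passed with a preset correlation between genes, among them mitosis, tubulin, ATF4 targets and other cell types, given below. Fold changes also followed GC content, as described further down. The rest were mitochondrially encoded transcripts and glycolysis genes, which rose, and DNA replication genes, which fell, by small amounts (camera, adjusted p = 6.08e-05, 9.36e-05 and 0.0403). With an estimated correlation none of these passed (adjusted p = 0.694 for each). At 2 residual degrees of freedom that form of the test has little power, so this decides little. The 13 protein-coding mitochondrial transcripts all had a log2 fold change above 0, with a median of 0.15. Of 21 glycolysis genes, 17 did, with a median of 0.15. With library totals alone in place of TMM factors, each of these medians was 0.05. Of 26 DNA replication genes, 21 had a log2 fold change below 0, with a median of -0.23, and this call ended whenever 1 library was left out. The median was then -0.11 without erianin replicate 2 and from -0.31 to -0.17 without each other library. The DNA replication call also ended with DESeq2 size factors (camera, adjusted p = 0.0504), upper-quartile factors (0.0528), a CPM of at least 1 (0.085) and the replicate number as a block (0.0584). No member of any of the 20 gene lists passed the test by itself. Across all genes 7 passed, and each of the 6 with a place in the annotation shares long stretches of sequence with a neighbour or near copy.

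AKT1 and AKT2, which encode AKT kinases, and MAP3K5, which encodes ASK1, did not pass the test. AKT1 (GRCh38 chromosome 14, 104769349 to 104795751, minus strand) had 341.8 CPM ± 6.51 in DMSO and 391.5 CPM ± 46.2 in erianin (SD, n = 2 each). Its log2 fold change was 0.20 with a standard error of 0.11 and an adjusted p of 0.576 from edgeR's quasi-likelihood test. AKT2 (chromosome 19, 40230317 to 40285536, minus strand) had a log2 fold change of 0.19 ± 0.11 (SE). MAP3K5 (chromosome 6, 136557047 to 136792518, minus strand) had 6.56 CPM ± 1.67 in DMSO and 5.71 CPM ± 2.01 in erianin (SD, n = 2 each). Its log2 fold change of -0.20 ± 0.30 (SE) became 0.08 without DMSO replicate 1 and 0.12 without erianin replicate 2. Over the fits that left out 1 library, the edgeR log2 fold change ran from 0.07 to 0.30 for AKT1 and for AKT2. The highest values, without erianin replicate 1, rest on erianin replicate 2, whose fold changes rose most steeply with GC content. Over all 20 alternatives the lowest values were 0.03 for AKT1 and 0.06 for AKT2. The GC content, as a fraction, was 0.621 for AKT1 and 0.583 for AKT2. Gene groups with median GC contents from 58.3% to 64.6% had median log2 fold changes from 0.14 to 0.18, not far below those of AKT1 and AKT2.

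Among the mitochondrial transcripts, MT-CYB, a subunit of complex III, had 2948 CPM ± 35.4 in DMSO and 3556 CPM ± 216 in erianin (SD, n = 2 each), a log2 fold change of 0.27 ± 0.10 (SE), and MT-CO2, a subunit of cytochrome oxidase, one of 0.25 ± 0.09 (SE). All transcripts of the mitochondrial genome, its ribosomal RNAs included, took 5.71% and 5.55% of all counts in the DMSO libraries and 6% and 6.06% in the erianin libraries. Among the glycolysis genes, the aldolase genes ALDOC and ALDOA had log2 fold changes of 0.30 ± 0.10 and 0.29 ± 0.11 (SE), and PFKL, which encodes liver phosphofructokinase, one of 0.27 ± 0.10 (SE). HK2, the gene of hexokinase 2, lay on the other side at -0.35 ± 0.19 (SE). Both groups passed in each fit that left out 1 library, at a highest adjusted p of 0.014 and 0.0413 without DMSO replicate 1.

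Among the genes of DNA replication, MCM6, a subunit of the replicative helicase, had 21.6 CPM ± 0.191 in DMSO and 14.5 CPM ± 1.48 in erianin (SD, n = 2 each), a log2 fold change of -0.57 ± 0.15 (SE). RRM1, of ribonucleotide reductase, had one of -0.39 ± 0.17 (SE). Genes of mitosis fell as a group too (adjusted p = 0.0202 with the preset correlation, and adjusted p = 0.694 with an estimated correlation), with 19 of 25 members below 0 and a median log2 fold change of -0.23. TOP2A, which encodes topoisomerase II alpha, had 39.2 CPM ± 3.92 in DMSO and 27.6 CPM ± 4.04 in erianin (SD, n = 2 each), a log2 fold change of -0.51 ± 0.15 (SE). CENPF and BUB1, genes of kinetochore proteins, had log2 fold changes of -0.57 ± 0.19 and -0.55 ± 0.17 (SE), and TTK, a checkpoint kinase, had one of 0.53 ± 0.22 (SE). The median of the mitosis genes against the DMSO mean was -0.09 in erianin replicate 1 and -0.33 in erianin replicate 2. The group call ended without erianin replicate 2 (adjusted p = 0.101) or DMSO replicate 1 (adjusted p = 0.114).

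Tubulin genes, some of them close paralogs between which reads can be divided, were all above 0 (11 of 11). They rose as a group by a median of 0.12 (adjusted p = 0.0234 with the preset correlation, and adjusted p = 0.731 with an estimated correlation). TUBA4A had 184.7 CPM ± 12.4 in DMSO and 217.6 CPM ± 21.1 in erianin (SD, n = 2 each), and the abundant TUBB had a log2 fold change of 0.11 ± 0.10 (SE). The median of the tubulin genes was 0.00 in erianin replicate 1 and 0.20 in erianin replicate 2. The call ended without erianin replicate 2 (adjusted p = 0.68) or DMSO replicate 1 (adjusted p = 0.274), and with library totals alone (adjusted p = 0.165). Targets of ATF4, the transcription factor of the amino acid and integrated stress responses, rose as a group by a median of 0.15, with 13 of 18 above 0 (adjusted p = 0.0234 with the preset correlation, and adjusted p = 0.694 with an estimated correlation). Their median was 0.06 without erianin replicate 2 and from 0.13 to 0.20 without each other library. With the GC and length trend removed it was 0.02. CHAC1, which degrades glutathione, had a log2 fold change of 0.30 ± 0.12 (SE), and DDIT4, an inhibitor of mTORC1, one of 0.23 ± 0.09 (SE). PSAT1, of serine synthesis, had one of -0.33 ± 0.14 (SE). This call held without erianin replicate 1 (adjusted p = 0.00999) and ended without erianin replicate 2 (0.111), DMSO replicate 1 (0.262) or DMSO replicate 2 (0.076), and with library totals alone (0.119).

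Markers of other cell types fell as a group (adjusted p = 0.0234 with the preset correlation, and adjusted p = 0.694 with an estimated correlation), with 7 of 9 measured members below 0 and a median of -0.52, and this rested on DMSO replicate 1. The median was -0.13 without DMSO replicate 1 and from -1.77 to -0.93 without each other library. COL3A1, a fibrillar collagen of fibroblasts, was at 8.83 CPM in DMSO replicate 1, 0.353 CPM in DMSO replicate 2, 0 in erianin replicate 1 and 0.216 CPM in erianin replicate 2. COL1A1 was at 9.27 CPM in DMSO replicate 1 and at 3.22, 2.92 and 3.42 CPM in DMSO replicate 2 and the erianin libraries. Without DMSO replicate 1 the adjusted p of the group was 0.495, and without erianin replicate 1 it was 0.207. The call also ended with library totals alone (0.057), limma-voom (0.0737) and a CPM of at least 1 (0.348).

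**Figure D1:**
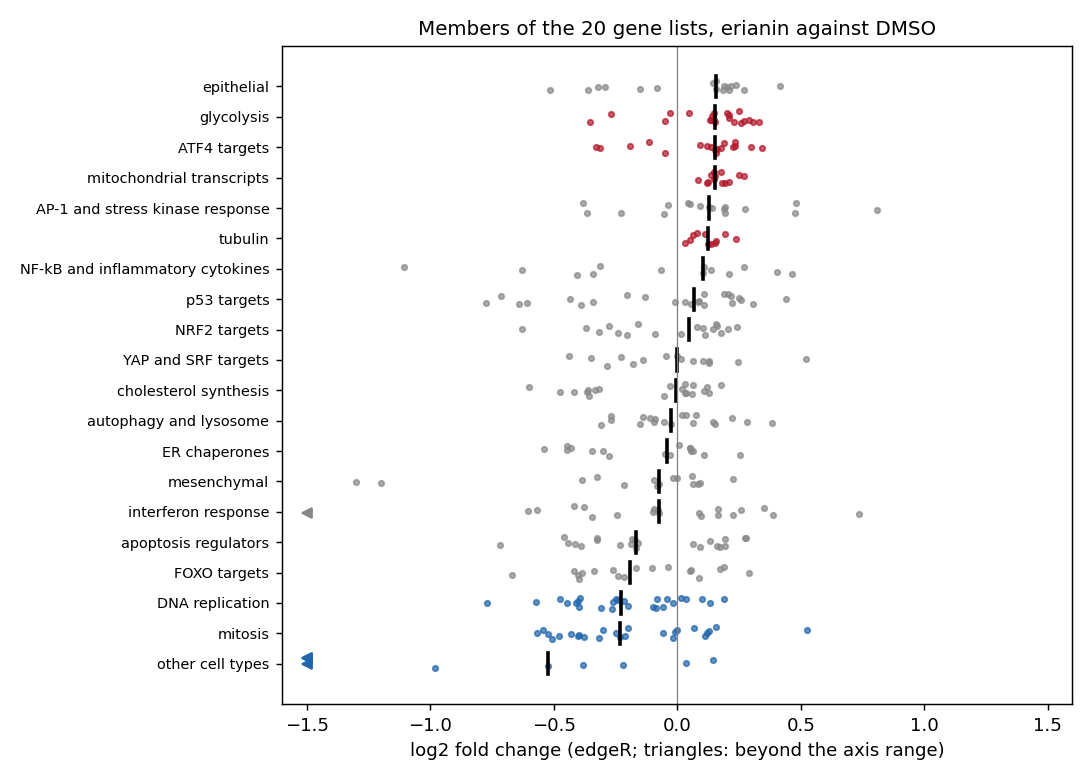
Log2 fold change of erianin against DMSO (x axis, edgeR) for the measured members of the 20 gene lists (y axis, 1 point per gene, black bar for the median). Lists past the threshold with the preset correlation are red (higher in erianin) or blue (lower), triangles mark genes beyond the axis range, and the 13 mitochondrial transcripts all lie above 0.

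The other 13 lists did not pass. ER chaperones came nearest, at an adjusted p of 0.0647, with CANX, an ER lectin chaperone, at -0.43 ± 0.14 (SE). They passed without erianin replicate 1 (adjusted p = 0.000154), with library totals alone (0.0218) and with the replicate number as a block (0.0118). The AP-1 and stress kinase response, which signalling through ASK1 is known to feed, had an adjusted p of 0.0906. It had 12 of 17 genes above 0 and FOSL1 at 0.27 ± 0.11 (SE). FOXO targets, which AKT is known to repress, had a median of -0.19 and an adjusted p of 0.332, with RICTOR at -0.67 ± 0.19 (SE). Targets of p53 went both ways (adjusted p = 0.865): GDF15 had a log2 fold change of 0.44 ± 0.12 (SE) and MDM2 one of -0.77 ± 0.27 (SE), while the median of the list was 0.07 and its mean -0.07. Apoptosis regulators (adjusted p = 0.791) had a median of -0.17, and BAK1, a pore-forming effector, was at 0.28 ± 0.12 (SE). NRF2 targets (adjusted p = 0.689, median 0.05, mean -0.05) included TKT at 0.24 ± 0.11 (SE). Cholesterol synthesis genes (adjusted p = 0.3, median 0.00, mean -0.13) included HMGCS1 at -0.60 ± 0.20 (SE) and passed with library totals alone (adjusted p = 0.0484). Genes of autophagy and the lysosome (adjusted p = 0.689) were tested as higher, with a median of -0.03, and included ATP6V0D1 at 0.28 ± 0.10 (SE). YAP and SRF targets (adjusted p = 0.766) had a median of 0.00 and included CRIM1 at -0.44 ± 0.13 (SE). Mesenchymal genes (adjusted p = 0.51) had a median of -0.07, with CDH2, N-cadherin, at -0.39 ± 0.15 (SE), and epithelial genes (adjusted p = 0.332) one of 0.16, with the tight junction gene TJP1 at -0.52 ± 0.15 (SE). The interferon response (adjusted p = 0.791) had a median of -0.08, with IFIT2 at -0.57 ± 0.14 (SE). NF-kB and inflammatory cytokine genes (adjusted p = 0.689) had a median of 0.10 and a mean of -0.09, with NFKB2 at 0.21 ± 0.09 (SE). The direction of the test was higher in erianin for the p53, NRF2 and NF-kB lists, whose means lay below 0. Of the 357 list members tested, 0 passed edgeR's test over all genes and 0 did when adjusted over the list alone, and 48 had an unadjusted p under 0.05. AKT2, CANX, ALDOC, ALDOA, MDM2, CDH2, TJP1 and IFIT2 are marked in the annotation as overlapping another gene, and their values are uncertain to that extent.

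Of 17090 genes tested, 2 rose and 5 fell at an adjusted p under 0.05, each by more than 2-fold. RAB4B-EGLN2 (chromosome 19, 40778242 to 40808418, plus strand), a read-through gene that joins RAB4B and the prolyl hydroxylase gene EGLN2, fell from 33.7 and 11.2 CPM in DMSO to 0.0628 and 0 CPM in erianin (edgeR, log2 fold change -9.31 ± 0.84, SE, adjusted p = 0.0176). The other 6 were named after their values had been seen. ENSG00000276612 (chromosome 21, 5116343 to 5133805, minus strand) fell from 36.2 and 40.3 CPM to 0 in both erianin libraries, at least 757-fold lower against a floor of 3 counts per library. It shares 85.9% of its longest transcript with ENSG00000280071, which had 47.8 and 52.2 CPM in DMSO and 92 and 99.1 CPM in erianin. RPL36A-HNRNPH2, another read-through gene, was at least 85.7-fold lower by the same floor. KBTBD11-OT1, which shares 88.4% of its longest transcript with ARHGEF10, was at least 77.9-fold lower. ENSG00000258790, which overlaps PRORP and PSMA6, fell from 18.5 and 9.95 CPM to 0.864 and 0.774 CPM. ENSG00000283765, which overlaps PARL and MAP6D1, rose from 0 in both DMSO libraries to 1.98 and 4.54 CPM, at least 69.7-fold. ENSG00000286235, which has no entry in the annotation used, rose from 0 to 15.1 and 5.26 CPM, at least 217-fold. When each of the 6 annotated genes was summed with the genes it shares sequence with, 0 of 6 passed and the log2 fold changes lay between -0.11 and 0.17. RPL36A-HNRNPH2, at 4.33 CPM in each DMSO library, was a small part of its sums of 540 and 516 CPM there. Where a gene is so small a part, its loss could not make the sum pass, whether or not reads moved. These 6 genes are uncertain as single genes, since the counting could divide reads between each of them and its partners. For ENSG00000286235 shared sequence was not examined.

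**Figure D2:**
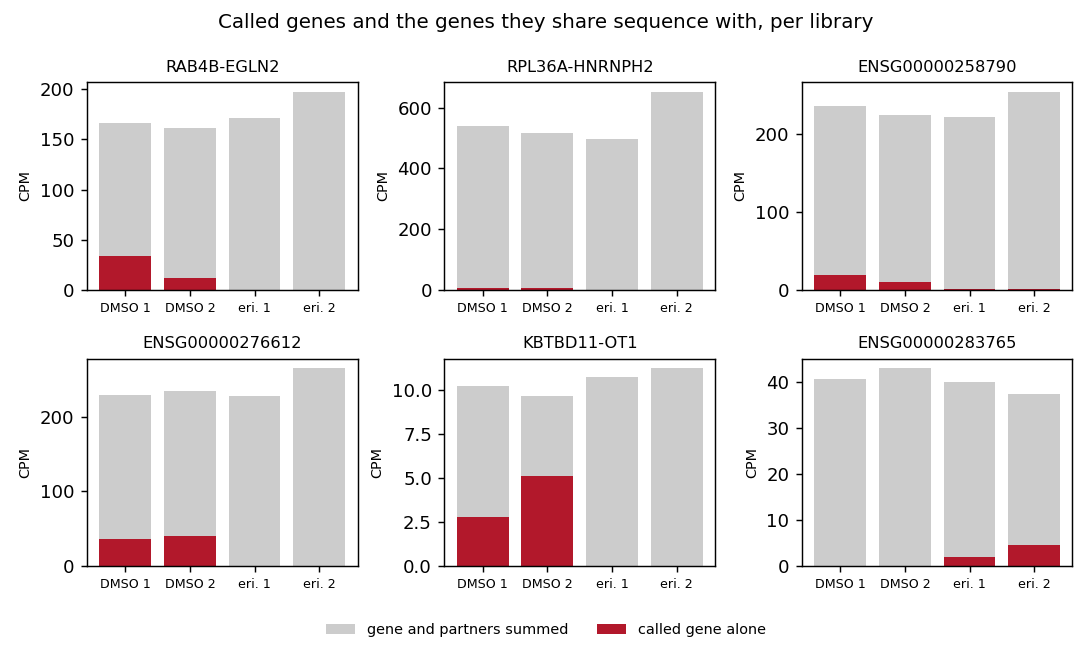
CPM per library (y axis) of 6 genes past the threshold (red) and of each gene summed with the genes it shares sequence with (grey, full bar height), for DMSO and erianin (eri.) replicates 1 and 2 on the x axis. ENSG00000276612 is at 36.2 and 40.3 CPM in DMSO and at 0 in erianin, while its sum with its partners runs from 228 to 265 CPM.

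At an unadjusted p under 0.05 there were 1385 genes, 378 higher and 1007 lower, against 854.5 expected if no gene differed and the p-values were exact. The other splits of the 4 libraries into pairs gave 358 and 253 such genes. Each of them mixes DMSO and erianin libraries, so any difference between the groups widens the spread within pairs and lowers the count. These splits therefore do not give the level of chance. Because the fold changes followed GC content, as given below, the excess and its direction cannot be assigned to erianin or to a GC bias of single libraries. Of the 8033 genes with a mean log2 CPM of at least 3, 98.1% lay within 1.5-fold. The split of 2 higher and 5 lower became 4 and 6 with upper-quartile factors, 0 and 2 with library totals alone, and 0 and 5 once each library's trend with GC content and length had been removed. The count of 7 became 62 without DMSO replicate 1, 73 without DMSO replicate 2, 24 without erianin replicate 2 and 3166 without erianin replicate 1.

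The erianin libraries differed from each other more than erianin replicate 1 differed from DMSO. The Spearman correlation across genes was 0.987 between the DMSO libraries, 0.985 and 0.986 between them and erianin replicate 1, 0.982 between the erianin libraries, and 0.978 and 0.981 between DMSO and erianin replicate 2. The log2 fold change of erianin against DMSO rose with the GC content of a gene (Spearman 0.663 across 8014 genes, which are not independent replicates), with a slope of 0.18 per 10 percentage points of GC. The slope was 0.19 between the erianin libraries and 0.05 between the DMSO libraries. With the trend of each library with GC content and length removed, the mitochondrial (adjusted p = 1.1e-16), glycolysis (0.00153), DNA replication (0.0111) and other cell type (0.0257) lists passed with the preset correlation. With an estimated correlation none of these 4 passed (adjusted p = 0.644, 0.654, 0.654 and 0.951). The removal raised the mitochondrial median from 0.15 to 0.25. That list has a median GC content of 44.3%. Genes near that GC content had a median log2 fold change of -0.19, so the offset itself lifted the list. Without DMSO replicate 1 as well, with the preset correlation, the glycolysis (0.105), DNA replication (0.105) and other cell type (0.838) calls ended. DNA replication also lost its call without DMSO replicate 2 (0.111) or erianin replicate 1 (0.0742), and other cell types without erianin replicate 1 (0.149). With the trend removed and all libraries kept, the mitosis (0.0638), ATF4 (0.826) and tubulin (0.918) lists lost their calls, and the direction of the tubulin test turned. Of the 25 genes named by rule, 20 had a log2 fold change smaller by over 1.5 times with the trend removed. It was -0.35 for MCM6, -0.22 for TOP2A, 0.08 for TUBA4A, 0.09 for CHAC1, 0.15 for ALDOC, -0.19 for CANX, 0.07 for FOSL1, 0.21 for GDF15 and -0.03 for MAP3K5. DDIT4, chosen after its values were seen, was at 0.04.

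**Figure D3:**
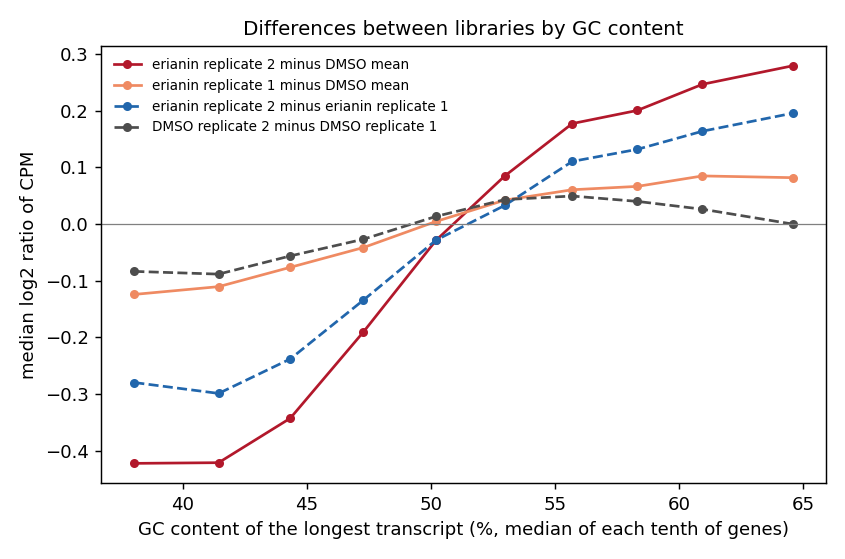
Median log2 ratio of CPM between libraries (y axis) in 10 equal groups of genes ordered by the GC content of the longest transcript (x axis, %). In the lowest GC group erianin replicate 2 lies at -0.42 and erianin replicate 1 at -0.12 against the DMSO mean, and erianin replicate 2 lies at -0.28 against erianin replicate 1.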

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

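Removal of the GC and length trend, overlapping genes summed, robust empirical Bayes and rows as deposited were chosen after seeing the data. The cause was not tested for any change below unless stated. Counts are given as all, higher, lower and at least 2-fold, against 7, 2, 5 and 7 in the main test. DESeq2 size factors in edgeR, no filter on low counts, a CPM of at least 1, a test against a 1.5-fold change and robust empirical Bayes left all of these within 1.5 times. Upper-quartile factors gave 10, 4, 6 and 9, and all 7 genes stayed among the 10. Library totals alone gave 2, 0, 2 and 2, and an adjusted p under 0.01 left 2 genes. DESeq2's Wald test gave 24, 12, 12 and 18, with all 7 among them. Limma-voom gave 0 of each, with 1673 genes at an unadjusted p under 0.05. FPKM with limma gave 2, 0, 2 and 2 at either pseudocount and 1, 0, 1 and 1 with no filter. Removing the GC trend gave 3, 0, 3 and 3, and the GC and length trend 5, 0, 5 and 5. With that trend removed, 12 genes passed without DMSO replicate 1, 35 without DMSO replicate 2, 677 without erianin replicate 1 and 16 without erianin replicate 2. Overlapping genes summed gave 1, 1, 0 and 1, and 0 of each with the GC and length trend removed too (edgeR, 1193 at an unadjusted p under 0.05). Rows as deposited gave 0 of each (edgeR, 2846 at an unadjusted p under 0.05, among 48163 rows). With 1 library left out, the lone library is assumed to vary like the other group, and the counts ran from 24 to 3166, 9 to 1322, 15 to 1844 and 22 to 352. Whether the replicate numbers pair the libraries is not known. Same-numbered deviations correlated across genes at Pearson 0.0553 and Spearman 0.258, with 2 pairs. Pairing the libraries the other way would only turn the sign, so this correlation cannot decide it. With the replicate number as a block, which leaves 1 residual degree of freedom, the counts were 334, 66, 268 and 99, and with the block and the GC and length trend removed 22, 13, 9 and 18. The number of lists past the threshold, 7, became 0 with an estimated correlation, 4 with the GC trend, the GC and length trend, or the block with that trend removed, 2 to 6 with 1 library left out, and 1 to 4 with 1 library left out and the trend removed. Of 19 alternatives, mitochondrial transcripts passed in 18, all but the estimated correlation, and glycolysis in 17, all but that and the trend removed without DMSO replicate 1 (adjusted p = 0.105). Other cell types passed in 11 of 19, mitosis in 9, tubulin in 8, and DNA replication and ATF4 targets in 7 each. The direction of the test reversed, with no adjusted p under 0.05, for tubulin, apoptosis regulators, autophagy and lysosome, and NF-kB genes with the GC and length trend removed (0.918 each) and with the block as well (0.961 each). It reversed for the last 3 and epithelial genes with the GC trend removed (0.974 each). It reversed for p53 targets in those fits (0.626, 0.568 and 0.75) and with the block alone (0.928), for NRF2 targets with library totals (0.984), and for the interferon response at a CPM of at least 1 (0.862). It also reversed in some of the 4 fits with 1 library left out, over which adjusted p ran from 0.786 to 0.982 for p53 targets, 0.739 to 0.982 for apoptosis regulators, 0.755 to 0.982 for the interferon response and 0.394 to 0.982 for YAP and SRF targets. The AP-1 and stress kinase response (without DMSO replicate 2 or erianin replicate 1) and FOXO targets (without erianin replicate 2) reversed only with the GC and length trend removed as well. Of the 25 named genes, MAP3K5 reversed in 2 of the fits with 1 library left out (log2 fold changes from -0.63 to 0.12). RAB4B-EGLN2 lost its call in 7 of 20 alternatives, and also with the GC and length trend removed without erianin replicate 2. Genes with no call in the main test passed without erianin replicate 1 (20 genes), with the block (6) and without DMSO replicate 2 (1). Depth limits genes near the floor of 3 counts per library (0.0505 CPM in erianin), while with 2 libraries per group 24.2% of simulated 1.5-fold changes were recovered.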

Other observations

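The tests of sequence partners, of the GC slopes between libraries, of the glycolysis list with the trend removed and of the number of genes under other splits were chosen only after the result was seen, and so were the bootstrap interval of the hypoxia genes and the binomial test of genes at 0, which changed both readings from decided to open. For glycolysis with the trend removed, the demand that the call hold with each library left out was also added later. It changed that reading to open too.

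CA9, carbonic anhydrase 9, a surface enzyme that acidifies the space around cells and a known target of hypoxia-inducible factor, had 1.79 and 1.49 CPM in DMSO and 6.06 and 6.8 CPM in erianin. Its log2 fold change was 1.97 ± 0.25 (SE) by edgeR, with an adjusted p of 0.096, and DESeq2's Wald test gave an adjusted p of 2.05e-05. NDRG1 and ANGPTL4, other known targets of that factor, had log2 fold changes of 0.39 ± 0.10 and 0.41 ± 0.12 (SE), and each was higher in both erianin libraries than in both DMSO libraries. The integrin gene ITGAV had 50.5 and 49.1 CPM in DMSO and 34.9 and 28.9 CPM in erianin. Its log2 fold change was -0.64 ± 0.15 (SE) by DESeq2's Wald test, with an adjusted p of 0.024, and edgeR gave an adjusted p of 0.575. With the GC and length trend removed the edgeR log2 fold changes were 1.76 for CA9, 0.38 for NDRG1, 0.20 for ANGPTL4 and -0.34 for ITGAV. These 4 genes were chosen after their values were seen.

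Glycolysis genes were higher in erianin, and with the GC content and length trend of the libraries removed the list passed with the preset correlation (camera, adjusted p = 0.00153). Its median log2 fold change was 0.08 after 0.15. With an estimated correlation the list did not pass, with the trend removed (camera, adjusted p = 0.654) or kept (0.694). Whether that trend is the whole cause cannot be told. With it removed, the call passed only with the preset correlation, and the test with an estimated one has little power here. The call also did not hold in each fit that left out 1 library. The median stayed above 0 in those fits, from 0.07 to 0.11. For a response to low oxygen, a hypothesis for glycolysis and CA9 together, 24 other hypoxia genes without CA9, NDRG1, ANGPTL4 and the glycolysis genes had a median log2 fold change of -0.08 (10 of 24 above 0, camera, unadjusted p of 0.43) and, with the trend removed, of 0.03 (13 of 24 above 0, unadjusted p of 0.473, 95% bootstrap interval over genes -0.12 to 0.14). A p over 0.2 had been set in advance as evidence against it, but that bound was too loose, since this interval includes the glycolysis median of 0.08, so a small shift stays open and the explanation cannot be told apart from none. Of the 3 ways to divide the 4 libraries into pairs, 1, the real one, called as many as 7 lists (highest other 1), and 3 splits are too few for a share under 0.05.

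The fold changes rose with GC content. Length in place of GC content was argued against by the partial Spearman correlation with GC given length, 0.638, beside -0.303 with length given GC. A GC bias of single libraries, apart from the treatment, is a candidate explanation. The slope between the 2 erianin libraries was 0.189 per 10 points, beside 0.179 for erianin against DMSO. The first value compares single libraries and the second group means, so they are not like for like. Against the DMSO mean the slope of erianin replicate 2 was 0.278. Erianin treatment cannot be told apart from such a bias. Erianin replicate 1 also had a slope of 0.0892 against the DMSO mean, above the 0.0456 between the DMSO libraries. The 2 erianin libraries could also differ in their response.

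Of the 7 called genes, the 6 with an annotation share sequence with neighbours or near copies. Reads moved between overlapping or near-identical genes may account for these calls. Summed with their partners, 0 of 6 remained past the threshold. Most were a small part of their sum, so a plain loss or gain of the gene could also leave the sum short of the threshold. RPL36A-HNRNPH2 held 4.33 CPM in each DMSO library, of sums of 540 and 516 CPM. KBTBD11-OT1 held a larger part, 2.76 and 5.11 of 10.2 and 9.66 CPM in DMSO, and its sum was 10.7 and 11.2 CPM in erianin. A switch between the transcripts of these genes brought about by erianin would leave the same sums, and 4 genes, 3 of them overlapping other genes, were at 2 CPM or more in both libraries of a group and at 0 in both of the other, against at most 2, 1 of them overlapping, for the other splits, which passed the bound of 1.5 times set in advance, but such counts are too few to decide (exact binomial test, two-sided, p = 0.687), so the switch cannot be told apart from moved reads. Of the 3 splits, 1, the real one, called as many as 7 genes (highest other 4), and 3 splits are too few for a share under 0.05.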
